A study of Mus musculus with 5 samples.

How the data were processed

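The series holds 5 samples from the TBV2 ESC line: H3K9me3 and H3K36me3 ChIP libraries from untreated cells and from cells given L-proline, and 1 input library from untreated cells. Per the labels' protocols, antibody-bound chromatin from sonicated nuclei was made into SOLiD fragment libraries with PCR amplification and sequenced on a SOLiD 4 instrument. Groups were taken from the sample titles, and each group had 1 library. Values of the input library were not analysed here.

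Per the submitters' processing notes, the islands were called with SICER on build mm9. SICER finds broad enriched regions by joining windows that pass a threshold. The SICER version, thresholds, the aligner, the treatment of duplicate reads and the use of the input as control are not given in the sources used here. Each deposited file lists the chromosome, start, end and a whole number for every island, with no header, and each file belongs to 1 library. The deposited whole number was read as the count of tags in the island, not scaled to library size, since SICER writes island lists in this layout. Every start was a multiple of 200 and every end lay on the same grid, so ends were taken as the last base of a 200 bp window counted from 0, and positions are given 1-based. No list held overlapping islands. The smallest gap between islands was 800 bp in both H3K9me3 lists and 1200 bp in both H3K36me3 lists, so the marks appear to have been joined over different gaps, and widths are not compared between marks beyond description.

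The gene table at hand was of GRCm38.p6. Islands reached position 197195400 on chromosome 1, past the last gene of that table at 195291439, and coordinates were not converted between builds. The comparisons of genes, genomic features and fixed gene lists that had been planned were therefore not made, and islands are reported by position.

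Lists were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Islands were called shared where they overlapped an island of the other list by 1 bp or more. For the level given by random placement, one list was rotated by a random distance around each chromosome, between the first and last base under any island, 1000 times with a fixed seed. This keeps widths and spacing but takes no account of gene-rich regions or of sequence that reads cannot be mapped to. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and ratios of island numbers the interval of the PiC share of both lists. The ratio between classes of windows carries a normal interval on the log scale. Bootstrap intervals, named as such, come from islands resampled with replacement. Islands are not independent replicates and PCR copies are not independent molecules, so these intervals cover counting error only and say nothing of the spread between cultures. With 1 library per condition no p-value was computed. The overlap functions were tested on simulated lists made from the ESC islands with 3 planted shares per mark. They found each planted share with an error of 0 percentage points, and an unrelated list gave 0.983 times the rotated overlap for H3K9me3 and 1.09 times for H3K36me3.

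The regions named were fixed by a rule written before the data were examined. For each mark they are the 3 widest islands of each list, the 3 with the most tags, and the 5 widest in each direction with no island of the same mark within 10 kb in the other condition. Tag counts describe and rank islands within their list, because the lists are not scaled to each other. Where tags per kb of both conditions are given for a site, they are unscaled and are not read as a gain or loss there. The comparison of tags per kb on chromosome 15 was made relative to other autosomes. Wide islands were those of at least 10 kb, and clusters were islands joined over gaps of up to 10 kb that spanned at least 50 kb. Alternatives were the 50% of each list with the most tags, lists of equal size, islands joined over 2 kb, a minimum width of 1 kb, autosomes alone, a reciprocal overlap of 50%, a distance of 2 kb counted as shared, and other limits for wide islands and clusters. Lists without chromosome 15, H3K36me3 islands joined over 5 kb, the overlap of the marks counted apart for islands of 1 condition and shared islands, the split of chromosome 15 and the comparison in 5 Mb windows were added after the data had been seen.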

Results

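Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map 2 histone marks in TBV2 mouse embryonic stem cells (ESCs), a line of the 129/SvP strain. H3K9me3, histone H3 trimethylated at lysine 9, is typical of silenced chromatin and repeats. H3K36me3, trimethylated at lysine 36, is typical of the bodies of transcribed genes. Each mark was profiled in untreated ESCs and in cells kept for 5 days with 500 µM L-proline, called L-proline-induced cells (PiCs). The question addressed was whether this amino acid alters where the 2 marks lie. Each mark and condition was represented by 1 library, so differences between ESCs and PiCs had no replicate check and no test between conditions was made. Intervals given below are 95% intervals over islands, and they cover counting error only. They are exact binomial intervals, apart from the normal interval of the ratio between classes of windows and those named as bootstrap intervals.

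The deposited lists held 18464 H3K9me3 islands in ESCs and 25867 in PiCs, and 12280 H3K36me3 islands in ESCs and 16804 in PiCs. The whole number attached to each island was read as its tag count. It summed to 1511058 tags in the ESC H3K9me3 islands and to 3514489 in those of PiCs. For H3K36me3 the sums were 26055650 tags in ESCs and 15787192 in PiCs. These sums cover called islands only, so the depth of the libraries is unknown. Islands are given by position on mouse build mm9, and no gene annotation of that build was used here.

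H3K9me3 islands covered more of the genome in PiCs than in ESCs. PiCs had 1.40 times as many H3K9me3 islands (interval 1.37 to 1.43), an addition of 7403 islands. In sum the PiC islands held 2.33 times the tags of the ESC islands. Whether a larger yield of tags accounts for the larger number and width of PiC islands was not tested. The covered length was 55.3 Mb in ESCs and 96.4 Mb in PiCs, a ratio of 1.74. Islands were also wider in PiCs, with a median of 3.2 kb against 2.6 kb. Wide islands of at least 10 kb numbered 194 in ESCs and 749 in PiCs, a ratio of 3.86 that was 2.44 for islands of at least 5 kb. Clusters of at least 50 kb, made by joining H3K9me3 islands over gaps of up to 10 kb, numbered 17 in ESCs and 119 in PiCs, and 5 and 24 with gaps of up to 5 kb.

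**Figure D1:**
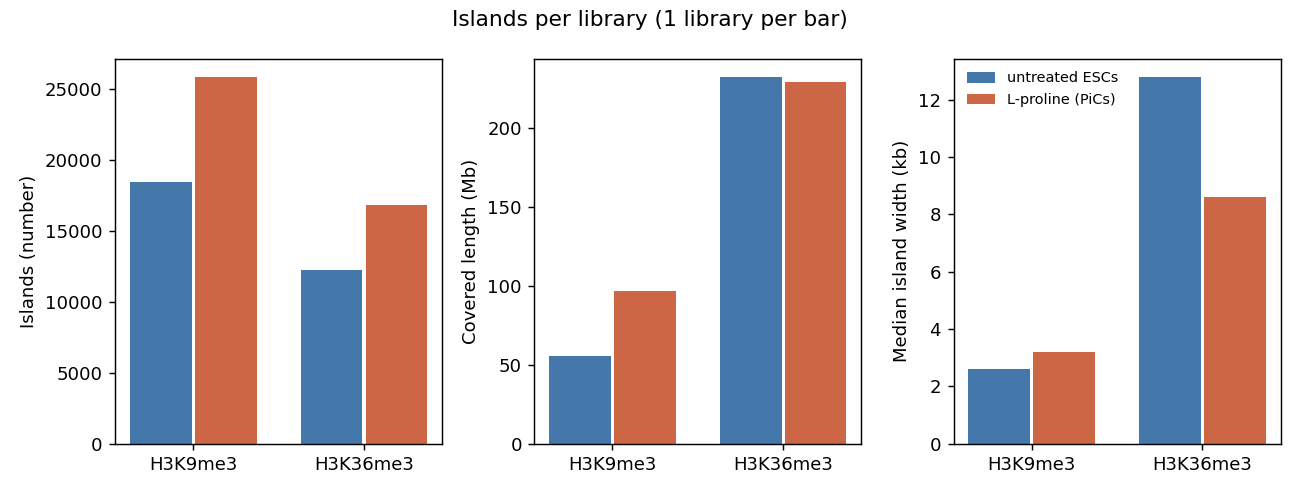
Bars give the number of islands, the covered length in Mb and the median island width in kb for each of the 4 libraries, with untreated ESCs in blue and L-proline-treated cells (PiCs) in orange. H3K9me3 went from 55.3 Mb in ESCs to 96.4 Mb in PiCs, whereas H3K36me3 covered 232.3 Mb and 229.2 Mb and its median island width was 12.8 kb and 8.6 kb.

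Most H3K9me3 islands of ESCs were also found in PiCs, while 45.5% of the PiC islands had no ESC counterpart. An overlap of 1 bp or more was found for 79.3% of the ESC islands (interval 78.7 to 79.8) and for 54.5% of the PiC islands (53.9 to 55.1). Much of this contrast follows from the longer PiC list. With lists of equal size the shares were 68.1% and 64.6%. Rotating one list around each chromosome 1000 times gave mean overlaps of 6.55% and 4.65%. The shared bases, 39.6 Mb, made up 71.5% of the ESC coverage and 41.0% of the PiC coverage. PiC-only H3K9me3 islands numbered 11760 and covered 34.9 Mb, whereas ESC-only islands numbered 3831 and covered 11.4 Mb. The ESC-only islands were sparse in tags, with a median of 17.5 tags per kb against 27.1 in the shared ESC islands. PiC-only islands had a median of 30 tags per kb against 35.7 in the shared PiC islands. Among the tenth of ESC islands with the most tags 98.3% were shared, and among the tenth with the fewest 66.5%. In PiCs these shares were 87.9% and 25.3%. Requiring an overlap of 50% of both islands lowered the shared portion of ESC islands to 52.6%.

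The 3 H3K9me3 islands with the most tags were the same in both conditions. The input library was not analysed, so these islands could not be told apart from sites that gather tags without the antibody. The island with the most tags lay on chromosome Y at 2847201 to 2902800, with identical edges in both lists and 349.0 tags per kb in ESCs and 917.7 in PiCs. It was followed by a 75.4 kb island on chromosome 11 at 3025601 to 3101000, which was also the widest of the ESC list and measured 73.0 kb in PiCs (3027201 to 3100200). A 5.6 kb island on chromosome 2 at 98502201 to 98507800 came next, with 910.2 tags per kb in ESCs and 1852 in PiCs, where the list medians were 25.5 and 33.0. The widest H3K9me3 islands of both lists also included one on chromosome 1 (90123201 to 90170400 in ESCs, 47.2 kb, and 90122001 to 90164000 in PiCs, 42 kb). In ESCs 34.7% of that island was covered by H3K36me3 as well.

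Of the H3K9me3 islands with none of the other condition within 10 kb, 8584 belonged to PiCs and 3115 to ESCs. The widest PiC-only island spanned 32.8 kb on chromosome 1 (173467401 to 173500200) and held 1730 tags, or 52.7 per kb. The next widest lay on chromosome 9 at 19951401 to 19972600 (21.2 kb), chromosome 7 at 5574401 to 5593800 (19.4 kb), chromosome 2 at 36341801 to 36356000 (14.2 kb) and chromosome 3 at 25428401 to 25442200 (13.8 kb). In that order they held 27.9, 30.9, 27.5 and 33.7 tags per kb, against a median of 33.0 for the PiC list. None of these 5 regions carried an H3K36me3 island in either condition. Of the 5 widest ESC-only H3K9me3 islands, 4 lay on chromosome 15, at 79336601 to 79350800 (14.2 kb), 75821801 to 75835800 (14 kb), 85396601 to 85408000 (11.4 kb) and 97650201 to 97661600 (11.4 kb). The other was on chromosome 1 at 78189601 to 78200800 (11.2 kb). These ESC-only islands held 14.6 to 16.7 tags per kb, below the median of 25.5 for the ESC list. The region at 75821801 was covered by H3K36me3 over 5.71% of its length in ESCs and 44.3% in PiCs. It was the only one of the 5 where this coverage differed. The region at 79336601 had 2.82% in both conditions, and those at 85396601, 97650201 and 78189601 had none in either.

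H3K36me3 lay in more and narrower islands in PiCs without covering more sequence. PiCs had 1.37 times as many H3K36me3 islands as ESCs (interval 1.34 to 1.40), an addition of 4524. In sum the PiC islands held 0.606 times the tags of the ESC islands. How the number of tags changes the number and width of the islands called was not tested. Covered length was 232.3 Mb in ESCs and 229.2 Mb in PiCs, a ratio of 0.987. The median width was 12.8 kb in ESCs and 8.6 kb in PiCs. Islands of at least 10 kb made up 61.9% of the ESC islands and 44.3% of the PiC islands. Their numbers were close, at 7597 and 7451, as were those of clusters of at least 50 kb, at 1663 and 1686.

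The ground covered by H3K36me3 was largely common to both conditions. Of the ESC H3K36me3 islands 89.7% (interval 89.2 to 90.3) overlapped a PiC island, and of the PiC islands 79.7% (79.0 to 80.3) overlapped an ESC island, against 16.3% and 13.9% after rotation. The shared bases came to 194.6 Mb, or 83.8% of the ESC and 84.9% of the PiC coverage. An ESC island met 2 or more PiC islands in 2169 cases (17.7%), whereas a PiC island met 2 or more ESC islands in 766 cases (4.56%). PiC-only H3K36me3 islands numbered 3418, with a median width of 5.0 kb, and ESC-only islands numbered 1260, with a median of 7.6 kb. With an overlap of 50% of both islands required, the shared portion of PiC islands was 49.96%.

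The H3K36me3 islands with the most tags were again common to both lists. The first was on chromosome 1 at 71604601 to 71698800 in ESCs, with 542.4 tags per kb, and at 71604201 to 71699600 in PiCs, with 203.3 tags per kb. The list medians were 71.3 tags per kb in ESCs and 48.9 in PiCs. The next ESC islands were on chromosome 4 at 32745601 to 32867600 and on chromosome 1 at 84716801 to 84834800. In PiCs the next were the same chromosome 1 region (84718401 to 84834800) and chromosome 4 at 138938001 to 139047800. The widest ESC island spanned 220.2 kb on chromosome 1 (120728601 to 120948800) and met 3 PiC islands that covered 96.5% of it. The other 2 widest ESC islands, on chromosome 11 at 8326601 to 8517200 and 119579001 to 119762000, met 5 and 8 PiC islands. The widest PiC islands lay on chromosome 10 at 6189001 to 6358800 (169.8 kb), chromosome 11 at 62117801 to 62269800 (152.0 kb) and chromosome 15 at 58766601 to 58912000 (145.4 kb).

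H3K36me3 islands with none of the other condition within 10 kb numbered 2177 in PiCs and 802 in ESCs. The widest of PiCs lay on chromosome 17 at 30766001 to 30851200 (85.2 kb), chromosome 1 at 94912201 to 94986800 (74.6 kb), chromosome 4 at 98071401 to 98106600 (35.2 kb), chromosome 3 at 51322601 to 51354800 (32.2 kb) and again chromosome 17 at 30876001 to 30907000 (31.0 kb). In the ESC H3K9me3 list, islands covered 8.85% of the chromosome 1 region, and in the PiC list none of it. The chromosome 17 region at 30766001 went the other way, with 1.41% in ESCs and 2.58% in PiCs. The remaining PiC-only regions named here carried no H3K9me3 island in either condition. In ESCs the widest were on chromosome 2 at 135750401 to 135815800 (65.4 kb), chromosome 5 at 65833801 to 65876600 (42.8 kb), chromosome 2 at 62168801 to 62207400 (38.6 kb), chromosome 17 at 68071601 to 68108600 (37.0 kb) and chromosome 10 at 61304001 to 61339200 (35.2 kb). H3K9me3 covered 5.95% of this chromosome 17 region in ESCs and 5.41% in PiCs. For the chromosome 10 region the values were 13.6% and 7.95%, and the others had none.

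The 2 marks overlapped less often than islands at rotated positions did, in both conditions. In ESCs 7.74% of H3K9me3 islands (interval 7.36 to 8.13) touched an H3K36me3 island, against a rotated mean of 10.4%. In PiCs the share was 6.07% (5.78 to 6.36), against 10.7%. The bases under both marks amounted to 4.47 Mb in ESCs and 5.54 Mb in PiCs. Counting from the other mark, 10.2% of ESC and 8.86% of PiC H3K36me3 islands touched an H3K9me3 island. With the 50% of each list that held the most tags the H3K9me3 shares were 5.04% in ESCs and 3.33% in PiCs. Few H3K36me3 islands had at least 50% of their length under H3K9me3, 1.83% in ESCs and 4.89% in PiCs.

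H3K9me3 islands found in 1 condition differed in where they lay relative to H3K36me3, a comparison added after the lists had been examined. Among ESC-only H3K9me3 islands 20.6% (interval 19.3 to 21.9) touched an ESC H3K36me3 island, and among shared ESC islands 4.37% (4.04 to 4.71). Among PiC-only H3K9me3 islands 3.95% (3.61 to 4.32) touched a PiC H3K36me3 island, and among shared PiC islands 7.83% (7.39 to 8.28). In the opposite direction, 19.9% of PiC-only H3K36me3 islands (18.5 to 21.2) touched a PiC H3K9me3 island, against 6.05% (5.65 to 6.47) of the shared ones. For ESC-only H3K36me3 islands and ESC H3K9me3 the share was 2.86% (2.01 to 3.93), against 11% (10.4 to 11.6) of the shared ones. The intervals of each pair did not overlap, but the classes differed in width and were not matched on it or on region. The class that touched less was the narrower one for PiC H3K9me3 (median 2.6 kb against 3.6 kb in shared islands) and ESC H3K36me3 (7.6 kb against 14 kb). PiC-only H3K36me3 islands touched more though narrower (5.0 kb against 10.6 kb). ESC-only H3K9me3 islands had a median of 2.8 kb against 2.6 kb. In the 5 Mb windows richest in H3K36me3, a class described below, lay 2255 of the 3831 ESC-only and 3335 of the 14633 shared ESC islands. There 27.5% of the ESC-only and 9.72% of the shared islands touched ESC H3K36me3. Random positions for the ESC-only islands in the same windows gave 25.2% (range 22.2 to 28.2). The ESC-only islands were thus near the random level for their region, and the shared ones lower.

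By chromosome, H3K9me3 islands were more numerous in PiCs on 18 of the 19 autosomes. The median autosomal ratio was 1.42 and the highest was 1.59, on chromosome 3. Chromosome 15 was the exception, with 1107 islands in ESCs and 1018 in PiCs, a ratio of 0.920 (interval 0.844 to 1.002), and a ratio of covered lengths of 0.940. Chromosome 11 had the next lowest ratio, 1.16 (1.06 to 1.28). Chromosome X had 742 islands in ESCs and 1361 in PiCs, a ratio of 1.83 (1.68 to 2.01). H3K36me3 ratios lay between 1.22 on chromosome 7 and 1.53 on chromosome 14, with 1.39 on chromosome 15. In covered length, H3K36me3 on these 3 chromosomes gave 0.987, 0.954 and 1.11, and the autosomal range ran from 0.921 on chromosome 9 to 1.11 on chromosome 15.

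**Figure D2:**
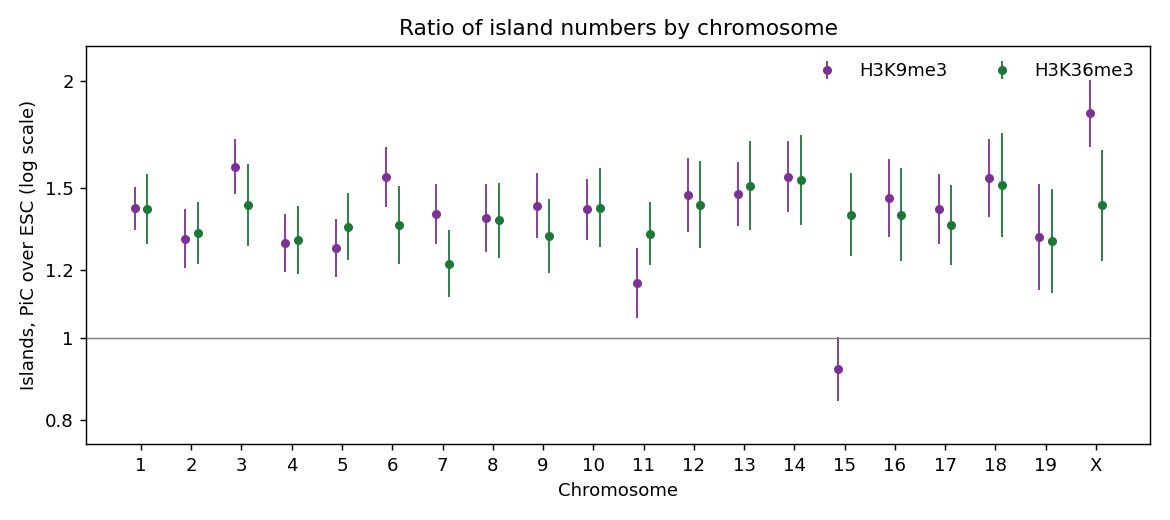
Points give the ratio of island numbers, PiC over ESC, on a log axis for chromosomes 1 to 19 and X, with H3K9me3 in purple, H3K36me3 in green and bars for exact 95% binomial intervals. Chromosome 15 is the only one with an H3K9me3 ratio below 1, at 0.920, and chromosome X has the highest, at 1.83; chromosome Y, with 25 ESC and 84 PiC H3K9me3 islands, is not drawn.

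The difference in H3K9me3 between the conditions varied with the H3K36me3 content of the region. This comparison was added after the lists had been examined. The genome was cut into 538 windows of 5 Mb, ranked by the share covered by ESC H3K36me3 islands and split into 4 equal classes. In the class poorest in H3K36me3 (134 windows, mean coverage 1.21%), there were 4356 H3K9me3 islands in ESCs and 7298 in PiCs, a ratio of 1.68 (interval 1.61 to 1.74). The ratio was 1.60 and 1.44 in the next classes. In the richest class (135 windows, mean coverage 19.1%) both conditions had 5590 islands, a ratio of 1 (0.963 to 1.04). With windows of 1 Mb the ratio was 1.73 in the poorest class and 0.930 (0.894 to 0.967) in the richest. Without chromosome 15 the richest class had a ratio of 1.05 (1.01 to 1.09), and its windows on chromosome 15 a ratio of 0.531 (0.458 to 0.614).

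**Figure D3:**
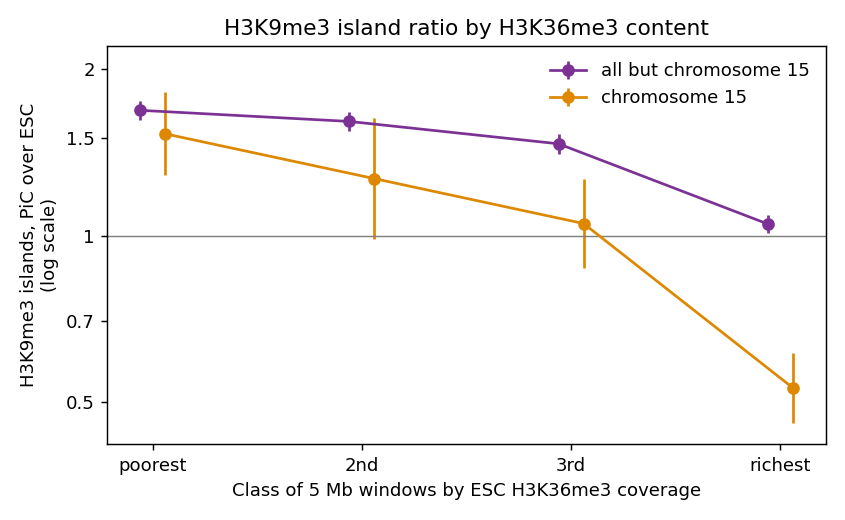
Points give the ratio of H3K9me3 island numbers, PiC over ESC, on a log axis in the 4 classes of 5 Mb windows from poorest to richest in ESC H3K36me3, with exact 95% binomial intervals. The ratio went by class from 1.68 to 1.05 on all chromosomes but 15 (purple) and from 1.53 to 0.531 on chromosome 15 (orange).

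On chromosome 15 the windows with more H3K9me3 islands in ESCs than in PiCs ran from 70000001 to 90000000 and from 95000001 to 105000000. The chromosome was split at 75 Mb, a point chosen from these values. Before it there were 559 islands in ESCs and 754 in PiCs, a ratio of 1.35 (interval 1.21 to 1.51). Past 75 Mb there were 548 and 264, a ratio of 0.482 (0.414 to 0.559). In the window from 75000001 to 80000000, ESCs had 126 H3K9me3 islands and PiCs 37, while H3K36me3 covered 27.5% of it in ESCs and 33.2% in PiCs. In the window from 90000001 to 95000000, where ESC H3K36me3 covered 3.48%, the H3K9me3 islands numbered 40 and 47. Among windows with at least 20 ESC islands, 10 had a ratio below 0.5, all in the class richest in H3K36me3. They were 3 of the 6 windows of that class on chromosome 15 and 7 of the 129 on other chromosomes. On chromosome 11 the window from 115000001 to 120000000 held 81 H3K9me3 islands in ESCs and 26 in PiCs, on chromosome 5 that from 120000001 to 125000000 held 46 and 15, and on chromosome 17 that from 25000001 to 30000000 held 75 and 33. These windows were chosen after their values were seen.

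**Figure D4:**
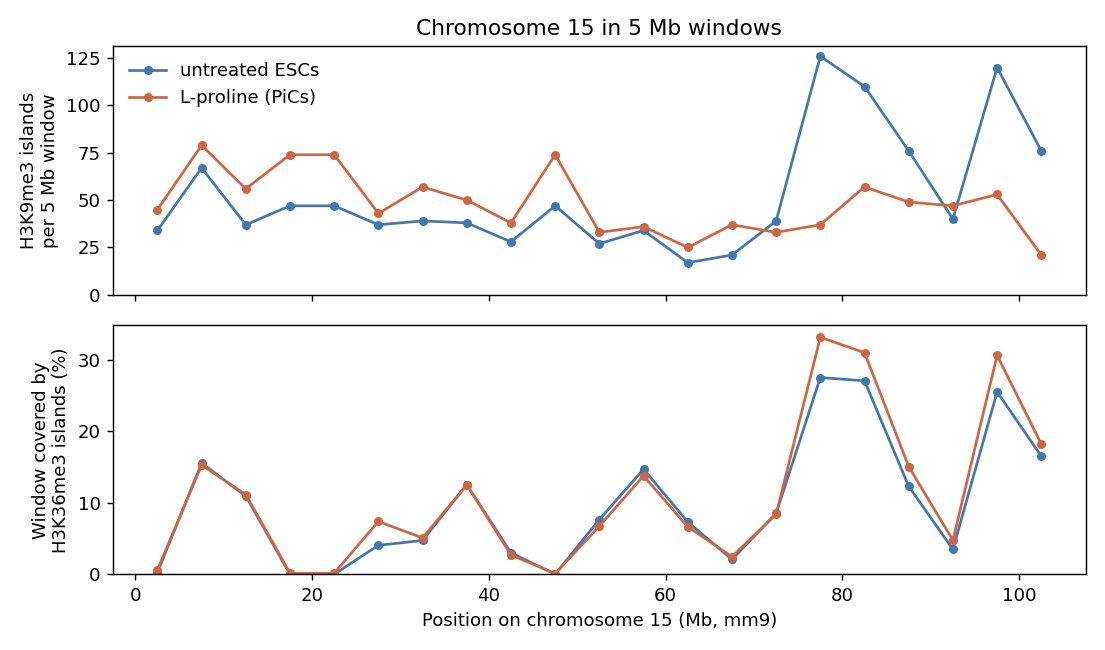
The upper panel gives the number of H3K9me3 islands and the lower panel the percentage covered by H3K36me3 islands in each 5 Mb window of chromosome 15 (mm9), with untreated ESCs in blue and L-proline-treated cells in orange. ESC H3K9me3 reaches 126 islands in the window from 75000001 to 80000000, where PiCs have 37.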

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

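With 1 library per condition, no setting could leave out a replicate. No paired analysis was possible because each group has 1 library. The H3K9me3 ratio in the class of 5 Mb windows richest in H3K36me3 changed side of 1 with its interval, from 1.05 (1.01 to 1.09) without chromosome 15 to 0.930 (0.894 to 0.967) with windows of 1 Mb and 0.703 (0.675 to 0.733) with lists of equal size. The poorest class went from 1.68 to 1.23 (1.18 to 1.28) with lists of equal size. Settings written as lists of equal size fix the ratio of island numbers at 1 by construction. For H3K9me3, the ratio of island numbers was 1.37 with islands joined over 2 kb, 1.45 with islands of at least 1 kb, and 1.43 without chromosome 15, a setting added later. The ratio of covered lengths was 1.81 with the better-scored 50% of each list, 1.51 with equal lists and 1.80 without chromosome 15. The shared portion of ESC islands was 78.5% with the better-scored 50%, 68.1% with equal lists, 80.5% without chromosome 15, 52.6% with reciprocal overlap and 80.4% with islands within 2 kb counted as shared. The shared portion of PiC islands was 64.6% with equal lists, 56.0% with islands joined over 2 kb, 52.8% with islands of at least 1 kb, 37.5% with reciprocal overlap and 57.5% within 2 kb. For H3K36me3, the number ratio was 1.26 when islands were joined over 2 kb and 1.21 over 5 kb, the latter added later. The ratio of covered lengths was 1.02 with the better-scored 50%, 0.913 with equal lists and 1.01 when joined over 5 kb, so its side of 1 depended on the setting. The shared portion of ESC islands was 93.5% with the better-scored 50%, 79.8% with equal lists, 90.6% when joined over 2 kb, 68.4% with reciprocal overlap and 90.6% within 2 kb. That of PiC islands was 77.0%, 88.7%, 78.9%, 49.96% and 81.4% under the same settings. H3K9me3 islands touching H3K36me3 came to 6.82% in ESCs and 5.51% in PiCs when 50% of the island had to be overlapped, 5.04% and 3.33% with the better-scored 50%, and 4.57% in PiCs with equal lists. H3K36me3 islands touching H3K9me3 came to 1.83% and 4.89%, 6.66% and 4.78%, and 6.41% in the same order. By covered length the H3K9me3 ratio was 1.29 on chromosome 11 and 2.12 on chromosome 3, and the H3K36me3 ratio 0.987 on chromosome 7 and 0.954 on chromosome 14, where the number ratios were above 1. At a limit of 5 kb the ratio of wide islands was 2.44 for H3K9me3 and 1.14 for H3K36me3. With gaps of up to 5 kb joined, the ratio of clusters was 4.8 (1.80 to 16.1) for H3K9me3, against 7 (4.19 to 12.4) as reported, and 0.954 (0.884 to 1.03) for H3K36me3. The cause of these shifts was not tested. The planned comparisons of genomic features, genes and gene lists were not run. Library depth is unknown, so absence of an island means only that none was called.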

Other observations

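The comparison in windows, the tests of yield and carry-over, the counts of exchange and the tests on chromosome 15 and on the islands of H3K36me3 found in 1 condition were chosen after the result was seen, and the other tests in this part were written down before it. Of the 3041 ESC-only H3K9me3 islands without H3K36me3 in ESCs, 257 (8.45%, interval 7.49 to 9.50) met a PiC H3K36me3 island. Of the 1224 ESC-only H3K36me3 islands without H3K9me3 in ESCs, 18 (1.47%, 0.874 to 2.31) met a PiC H3K9me3 island. No chance level was computed for either, and the marks differ in covered length, so no direction is read from these shares. Chromosome Y had 25 H3K9me3 islands in ESCs and 84 in PiCs, and 7 and 9 H3K36me3 islands.

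H3K9me3 islands were 1.68 times as numerous in PiCs as in ESCs where H3K36me3 was sparse, against a ratio of 1 where it was dense. The latter depended on the setting, at 0.930 with windows of 1 Mb, 1.05 without chromosome 15 and 0.703 (0.675 to 0.733) with lists of equal size, where the poorest class had 1.23 (1.18 to 1.28). With both lists cut to 50% of the shorter one the classes had 1.26 and 0.690. Suppose a larger yield in the PiC library scaled the tags of all islands alike and so kept their order. It would then leave no difference between the classes in lists of the same size. The ratio of the poorest over the richest class was 1.68 (interval 1.59 to 1.77) as deposited and 1.75 (1.65 to 1.85) with lists of equal size. With both lists cut to 50% of the shorter one it was 1.82 (1.68 to 1.97). These values argue against such an even scaling as the whole cause. A bound on the ratio within each class, written before, was replaced by this test, since lists of equal size fix the overall ratio at 1, and with the better-scored 50% of each list the richest class had 0.962 (0.912 to 1.01). A yield that differs between regions, or between marked sites and background, stays open, since it can change the order of islands by tags. Carry-over of H3K36me3-marked chromatin into the ESC H3K9me3 library is argued against as the whole cause. Among H3K9me3 islands that touched no H3K36me3 island of either condition the poorest over richest ratio was 1.47 (1.39 to 1.55), with 1.15 (1.104 to 1.199) in the richest class, and among those with none within 10 kb it was 1.39 (1.31 to 1.47). Carry-over as a part of the pattern stays open, since these values lie below 1.68, and since in the richest class 27.5% of the 2255 ESC-only islands touched ESC H3K36me3 islands against 9.72% (8.73 to 10.8) of the 3335 shared ESC islands. A test against random positions, written before, gave 1.09 (1.02 to 1.17), below its bound of 1.5, and was dropped because such positions do not give the level without carry-over. L-proline treatment cannot be told apart from a difference between single libraries, because there was 1 H3K9me3 library per condition. A difference in the recovery of open or GC-rich chromatin was not tested, as no mm9 sequence was used here.

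On chromosome 15 the H3K9me3 ratio of 0.920 was 0.695 times that expected from the H3K36me3 classes of its windows. The other autosomes lay between 0.925 and 1.07 times. The trend over the 4 classes on the other chromosomes gives an expected ratio of 1.32, outside the interval of 0.844 to 1.002. This expectation gives every window of a class the same ratio, so it leaves out any trend within a class. On other chromosomes, windows with at least 25.1% ESC H3K36me3 coverage had ratios of 0.321 to 1. Those on chromosome 15 had 0.294 to 0.518. The expected ratio may thus be too high for chromosome 15, since coverage was not matched within classes. A full extra copy of chromosome 15 in the untreated cells would lower the PiC over ESC tag density at matched islands by 0.58 on the log2 scale, but the difference from other autosomes was -0.089 (bootstrap interval -0.14 to -0.04) over 457 islands, and -0.081 (-0.20 to 0.01) over the 115 past 75 Mb. At 386 matched H3K36me3 islands of chromosome 15 the difference was 0.19 (0.14 to 0.25), in the opposite direction, and 0.25 (0.17 to 0.31) over the 239 past 75 Mb. Windows with at least 20 ESC islands and a ratio below 0.5 were picked for their low ratio. They made up 3 of the 6 windows richest in H3K36me3 on chromosome 15 and 7 of the 129 on other chromosomes. The 129 also count windows with fewer than 20 ESC islands, and coverage was not matched, so these shares are not like for like. An extra copy in a small share of the cells, a local difference in background and a response to L-proline all stay open. A trend with H3K36me3 within the richest class stays open as well.

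H3K36me3 had 1.37 times as many islands in PiCs over nearly the same length. If fewer tags in the PiC library split the ESC islands, the split ones should be sparser in tags. They held 0.608 times (bootstrap interval 0.588 to 0.625) the tags per kb of unsplit ones at matched width. Sparse islands could also split first under a different background level or threshold or a response to L-proline, so this value does not tell these apart. Isolated PiC-only H3K36me3 islands were 2.71 times (2.502 to 2.947) as numerous as isolated ESC-only ones. For those islands fewer tags cannot be told apart from a different background level or threshold in the PiC library or from a response to L-proline, because this ratio restates the pattern and no table tests how the number of tags changes the islands called.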
